A study of Mus musculus with 9 samples.

How the data were processed

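Paired-end RNA sequencing, with reads of 150 bases from a stranded kit, was done on hearts of mice aged 12 weeks in 3 genotype groups of 3 libraries each. The groups were wild-type mice and mice heterozygous or homozygous for an edited Rbm20 allele that lacks 2 bases and shifts the reading frame at codon 374. Groups were taken from the sample titles, and no sample was left out. The labels do not state whether each library came from a separate mouse, so p-values measure the spread between these libraries.

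The deposited table lists 480017 exonic parts, which are the pieces of exons bounded by annotated exon edges, under 54660 gene identifiers on the genome build GRCm39. For each part and library the authors deposited inclusion counts, which are reads assigned to the part, and exclusion counts, which are junction reads that skip it. The authors also deposited the percent spliced in (PSI) as a fraction from 0 to 1. Every deposited PSI was checked to equal inclusion reads divided by the part length plus 148 bases, over that value plus exclusion reads divided by 148 bases, with a largest gap of 5.0e-07. The other deposited column used is the part length in bases. The submitters' processing notes name cutadapt 1.8 and Salmon 1.2.1 and give no role for either, and they do not say which tool counted the parts or whether the strand was used. From the PSI formula, which adds 148 bases to the part length, it was inferred that a read spanning several parts was counted in each. Parts of overlapping genes, 44018 in number, carry a joined identifier and were kept under it. Whether a part is coding or untranslated was not annotated here.

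Inclusion counts summed to between 297 and 323 M reads per library and exclusion counts to between 52.6 and 62.3 M reads. The tested parts had a median of 122 inclusion plus exclusion reads per library.

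A part was tested if it had a PSI in all 9 libraries, at least 10 inclusion plus exclusion reads in each, a highest PSI of at least 0.05 and a lowest PSI of at most 0.95. These filters ignored the groups and left 55648 parts of 10688 gene identifiers, of which 7471 parts were shared by genes. PSI was fitted with limma 3.58.1 (lmFit, eBayes with a variance trend) over all 9 libraries with 6 residual degrees of freedom. A part was called at a Benjamini-Hochberg adjusted p under 0.05 and a PSI difference of at least 0.1 in size. For expression, inclusion counts were summed per gene identifier and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) in 22049 genes, called at an adjusted p under 0.05. If a read is counted in each part that it spans, a sum per gene exceeds the number of reads. CPM are counts scaled to library size with the TMM factors. R 4.3.3, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

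Gene lists were fixed from general knowledge of the heart: RBM20 targets, calcium handling and ion channels, sarcomere and Z-disc, cell junction and nuclear envelope cardiomyopathy genes, splicing regulators, cardiac stress genes, and markers of fibroblasts, endothelium, smooth muscle, macrophages and leukocytes, erythroid cells and atria. For parts, the number of list genes with a called part was compared with 10000 random gene sets matched on the number of tested parts per gene, in a one-sided permutation test, adjusted over the 12 lists of each comparison. For expression, fry from limma tested whether the genes of a list move, on balance, one way, which is not a comparison with other genes, adjusted over the lists of both comparisons together. Its mixed test, which counts movement in either direction, was adjusted in the same way. Both fry tests were run on the main design only and not under the alternatives. The number of parts called in both mutant groups was set beside 50 simulations of unchanged groups that shared the wild-type libraries. The 3 wild-type libraries were too few to divide between the comparisons.

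The parts and genes named in the text were set by a rule. For parts, these were Rbm20, each RBM20 target with a tested part, and the 15 further genes with the largest called PSI difference (5 for homozygous against heterozygous) whose groups did not overlap, with 1 part per gene. Some genes that met this rule are not reported here. A target was represented by its called part with the largest difference or, with none called, by the part with the smallest p. For expression, the rule named Rbm20, the cardiac stress genes and the 10 largest called changes in each direction whose groups did not overlap. Genes named outside this rule are examples from the lists or were chosen after their values were seen. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

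The alternatives for parts were a logit scale with 0.01 added, no filter on constant parts, minimums of 20 and 5 reads, PSI difference thresholds of 0.05 and 0.2, only the 2 groups compared, no variance trend, a quasi-binomial test on the reads, a replicate block, a covariate for the 2 runs of library numbers, genes counted in place of parts, and each library left out in turn. For expression they were DESeq2 1.42.0 with its size factors, no low-count filter, only the 2 groups compared, the replicate block, the library number covariate and each library left out. Those chosen after seeing the data were parts of a single gene only, removal of a junction shared by Ttn parts in 1 wild-type library, and, for expression, only parts with a mean PSI of at least 0.95.

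Both tests were tested on simulated data with 200 changed features in the homozygous group. For PSI, limma found 51% of changes of 0.4 and 8% of changes of 0.2, with 4 false among 63 calls. For expression, edgeR found 78% of 2-fold and 35% of 1.5-fold changes, with 7 false among 120 calls. The changed parts were drawn from those with an intermediate share of inclusion reads, and the changed genes from those with a mean count over 200. Recovery was not measured for parts that start near a PSI of 0 or 1 or for genes with few reads. The simulated noise for PSI was revised once, after a first version overstated the noise of the real libraries.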

Results

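The series asked how a frameshift allele of Rbm20, which encodes a splicing repressor of heart and skeletal muscle, alters the splicing of heart genes in mice. Hearts of wild-type, heterozygous and homozygous knock-in mice aged 12 weeks were sequenced, with 3 libraries per genotype. Inclusion reads summed to between 297 and 323 M per library, and mitochondrial genes took between 16.9% and 19.7% of them. PSI values are given as mean ± SD over the 3 libraries of a group, as fractions, with coordinates on GRCm39.

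The first comparison, homozygous against wild-type, asked which exonic parts changed their inclusion when both Rbm20 alleles carried the frameshift. Ttn, which encodes titin, the giant elastic protein of the sarcomere, dominated the result, with 148 of its 375 tested parts called, all of them higher in homozygous hearts. Camk2d, Ldb3 and Ryr2, which serve calcium signalling, the Z-disc and calcium release, also rose in inclusion. Altogether 230 parts of 56 gene identifiers were called by limma, 209 higher and 21 lower, and outside Ttn 61 parts rose and 21 fell. At an unadjusted p under 0.05 there were 4281 parts.

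The called Ttn (ENSMUSG00000051747) parts lay between parts 128 and 332 of the gene, from base 76632575 to base 76733970 of chromosome 2, and covered 20838 bases. Their median PSI was 0.0406 in wild-type, 0.147 in heterozygous and 0.964 in homozygous hearts, and their differences between homozygous and wild-type ran from 0.396 to 0.987. The largest was at part 250, a part of 102 bases at 76687147 to 76687248, with a PSI of 0.0042 ± 0.0049 in wild-type and 0.991 ± 0.0157 in homozygous hearts (n = 3 each, adjusted p = 8.68e-06). Wild-type replicate 2 held 339 exclusion reads shared by parts 3 to 386 of Ttn, where the other 8 libraries shared 0, which lowered its PSI over most of the gene. With these reads removed, 162 Ttn parts were called.

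Among the 28 genes listed as RBM20 targets, 26 had a tested part and 5 had a called one, namely Camk2d, Ldb3, Myh7, Ryr2 and Ttn. Matched random gene sets held 0.4 such genes on average, and the permutation p of 1e-04 (adjusted 6e-04) was the smallest that the permutations can give. Camk2d (ENSMUSG00000053819), a calcium- and calmodulin-dependent kinase, included part 50 (55 bases, chromosome 3, 126599511 to 126599565) at 0.131 ± 0.0354 in wild-type and 0.857 ± 0.0195 in homozygous hearts (n = 3 each, adjusted p = 4.73e-05). In the same gene, the neighbouring parts 46 and 47 fell, part 47 from 0.245 to 0.0863 (adjusted p = 0.0159). Ldb3 (ENSMUSG00000021798), a Z-disc scaffold, rose at part 18 (8 bases, chromosome 14, 34293871 to 34293878) from 0.0609 ± 0.0044 to 0.724 ± 0.0237 (adjusted p = 1.83e-05), while its parts 20 and 21 fell, part 21 from 0.975 to 0.452. Ryr2 (ENSMUSG00000021313), the calcium release channel of the sarcoplasmic reticulum, rose at part 32 (24 bases, chromosome 13, 11649193 to 11649216) from 0.023 ± 0.0036 to 0.361 ± 0.0206 (adjusted p = 2.06e-05).

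The other 21 targets with a tested part were not called. At the part with the smallest p of each, the largest differences among the targets reported here were at Pdlim5 part 16 (0.216, adjusted p = 0.137) and Lmo7 part 23 (0.215, adjusted p = 0.2). Those of Trdn, Camk2g, Cacna1c, Tpm1, Tnnt2, Nexn, Pdlim3, Rtn4, Lrrfip1, Enah, Kcnip2, Ktn1, Mlip, Sh3kbp1, Spen and Dtna ranged from -0.157 to 0.131. Adjusted over the list alone, 208 parts of 11 targets passed, with Camk2g, Lmo7, Mlip, Pdlim5 and Trdn among those added. Rbm20 itself rose at part 11 (13 bases, chromosome 19, 53831641 to 53831653), from 0.0897 ± 0.0108 to 0.261 ± 0.0401 (adjusted p = 0.0289), and Myh7, a myosin heavy chain, at part 45, from 0.0349 ± 0.0038 to 0.176 ± 0.0387 (adjusted p = 0.016). Each of these last calls was lost under 11 of 20 alternatives, with adjusted p from 0.00869 to 0.255 for Rbm20 and from 7.94e-05 to 0.176 for Myh7, and the losses included leaving out any of the wild-type libraries.

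**Figure D1:**
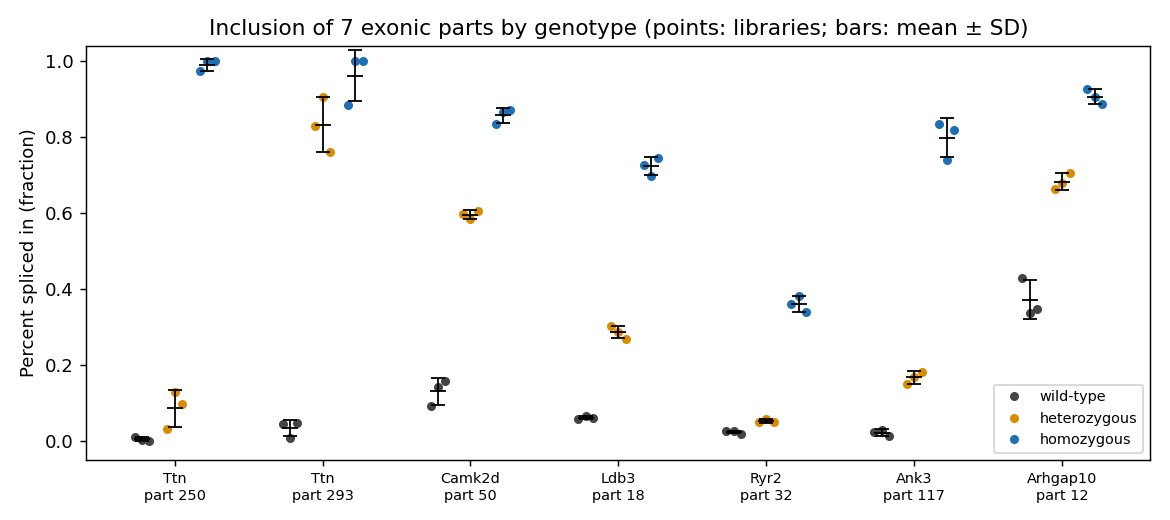
PSI (fraction, vertical axis) of 7 exonic parts (horizontal axis) in each genotype, with points for the libraries and bars for the mean ± SD of 3 libraries. In each part the homozygous mean was the highest, and at Ttn part 293 the heterozygous mean of 0.833 came close to the homozygous mean of 0.962.

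Outside the target list, the named genes with the largest differences rose, apart from 3 that fell. Ank3, which encodes ankyrin-G, a membrane anchor for ion channels, rose at part 117 (84 bases, chromosome 10, 69849802 to 69849885) from 0.0218 ± 0.0081 to 0.798 ± 0.0513 (adjusted p = 1.33e-05), and 4 of its parts were called. Arhgap10, a GTPase activator, rose at part 12 from 0.372 ± 0.0506 to 0.907 ± 0.0187 (adjusted p = 0.000458). The uncharacterised 2310002L09Rik rose at part 1 from 0.0552 ± 0.0488 to 0.999 ± 0.0021 (adjusted p = 7.85e-05). E430018J23Rik, Zfp458, Ccdc173, Msh3, Gm29015, Mhrt, Fhl1 and Ttc17 also rose, by 0.343 to 0.784. Scube2, Gm26782 and Slc35a2 fell, by 0.429, 0.413 and 0.389. Calls at E430018J23Rik, Msh3, Scube2, Mhrt, Gm26782, Fhl1, Slc35a2, Ttc17, Gm29015 and Zfp458 were lost under between 1 and 14 of their alternatives. The named parts of Mhrt and Gm29015 overlap the span of Myh7 on chromosome 14. Whether the strand was used in counting was not stated, so they may hold reads of Myh7.

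By gene list, 5 sarcomere and Z-disc genes had a called part, namely Fhl1, Ldb3, Myh7, Myom1 and Ttn (0.33 expected, permutation p = 1e-04, adjusted 6e-04, the smallest the permutations can give). Of the 639 tested parts in the 27 tested genes of this list, 155 rose, 148 of them in Ttn, and 2 fell, and 8 genes passed when adjusted over the list alone. Calcium handling and ion channels had calls in Camk2d and Ryr2 (0.18 expected, permutation p = 0.0118, adjusted 0.0472), where 3 parts rose and 2 fell, and 3 genes passed when adjusted over the list alone. Splicing regulators had 1 gene with a call, Rbm20 (adjusted p = 0.602), and cardiac stress genes 1, Myh7 (adjusted p = 0.165), each with the same number when adjusted over the list alone. Cell junction and nuclear envelope genes and the markers of fibroblasts, endothelium, smooth muscle, macrophages and leukocytes, erythroid cells and atria had 0 genes with a call by limma, also when adjusted over the list alone. The number of lists past the threshold was 3 and fell to 1 without wild-type replicate 1, wild-type replicate 2 or heterozygous replicate 2. The 3 lists share genes, since Camk2d, Ryr2, Ldb3, Myh7 and Ttn are also the called RBM20 targets, so they are not separate results.

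The comparison of heterozygous with wild-type hearts asked what a single frameshift allele does. Ttn and Camk2d rose in inclusion in heterozygous hearts, and few other genes were called. Ttn part 293 (279 bases, chromosome 2, 76715469 to 76715747) rose from 0.0331 ± 0.0217 to 0.833 ± 0.0725 (n = 3 each, adjusted p = 0.00432), and Camk2d part 50 to 0.596 ± 0.0117 from 0.131 ± 0.0354 (adjusted p = 0.00891). Altogether 42 parts of 12 gene identifiers were called by limma, 41 higher and 1 lower, of which 27 were in Ttn, and 2248 parts had an unadjusted p under 0.05.

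The 10 further genes in heterozygous hearts were Zfp458, Ccdc173, Msh3, Pcnt, Trim12a, Ppa2, H2bc4, Aox1 and the pseudogene Ppp4r1l-ps, which rose by 0.159 to 0.684, and the Npff, Gm28047 and Atf7 locus, which fell at part 7 from 1 in all 3 wild-type libraries to 0.794 ± 0.0456 (adjusted p = 0.0249). The first 8 of these are taken up in the closing section, where sequence variants stay open as the source of their change. Each of the 10 calls was lost under some alternatives, from 2 of 19 at Pcnt to 14 of 20 at Trim12a. The fall at the Npff locus was lost under 13 of 19, including each wild-type library left out, with adjusted p up to 0.638. Ccdc173 was lost under 10 of 19 and Ppp4r1l-ps under 8 of 19. Pcnt, which encodes the centrosome protein pericentrin, went from 0.702 ± 0.0101 to 0.997 ± 0.0056 (adjusted p = 0.00432), and Ppa2, a mitochondrial pyrophosphatase, from 0.789 ± 0.0131 to 0.978 ± 0.0065 (adjusted p = 0.00891). The parts of Pcnt and Ppp4r1l-ps carry identifiers joined with the overlapping AC141477.1 and ENSMUSG00000121504, so their change cannot be credited to 1 gene. Ldb3 part 18 had a PSI of 0.286 ± 0.0161 in heterozygous hearts (difference 0.225, adjusted p = 0.101), and Ryr2 part 32 one of 0.0519 ± 0.0057 (adjusted p = 0.968). Other targets had adjusted p values of at least 0.248, the lowest at Tnnt2 part 14, and the Rbm20 part with the smallest p was part 1 (difference -0.0373, adjusted p = 0.968).

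Of the 26 tested targets, 2 had a called part, Camk2d and Ttn, where matched sets held 0.23 on average (permutation p = 0.0155, adjusted 0.186), and 4 genes with 105 parts passed when adjusted over the list alone, with Ldb3 and Tnnt2 added. Tnnt2 part 14 averaged 0.811 in wild-type, 0.996 in heterozygous and 0.857 in homozygous hearts, so its change did not grow with the second frameshift allele. Of the other lists, sarcomere and Z-disc had a call in Ttn (adjusted p = 0.836) and in 4 genes adjusted over the list alone, and calcium handling and ion channels in Camk2d (adjusted p = 0.264) and in 1 gene adjusted over the list alone. The remaining lists had 0 genes with a call by limma, also when adjusted over the list alone. These heterozygous calls depended on the fit, since 0 parts were called with only the 2 groups compared and 0 with the replicate block, and 15 with no Ttn part among them on the logit scale. Without heterozygous replicate 1 there were 3 parts and 0 targets, without wild-type replicate 3 there were 25 parts, and without homozygous replicates 1, 2 and 3 there were 23, 18 and 18.

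Of the parts called in heterozygous hearts, 40 were also called in homozygous hearts in the same direction, 27 of them in Ttn and 13 in other genes. The 13 were 2 parts of Camk2d and the 11 parts of the 8 genes for which sequence variants stay open. Simulated unchanged groups that shared the wild-type libraries gave 0.02 such parts on average and 1 at most in 50 simulations. With no change in any simulated group, few parts could be called in either comparison. The simulations therefore cannot show how far shared controls raise the overlap beside a real homozygous change. Independent lists would give 0.154 higher and 0.000377 lower, without regard to the shared wild-type libraries. Across tested parts, which are not independent, the covariance of the PSI differences was 0.00267 against 0.00126 simulated, and their correlation was 0.487 against 0.499 simulated, so the shared controls alone gave a correlation of that size. The overlap was 1 part without heterozygous replicate 1, 18 without heterozygous replicate 2, 25 without wild-type replicate 3, and 22, 17 and 17 without homozygous replicates 1, 2 and 3.

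**Figure D2:**
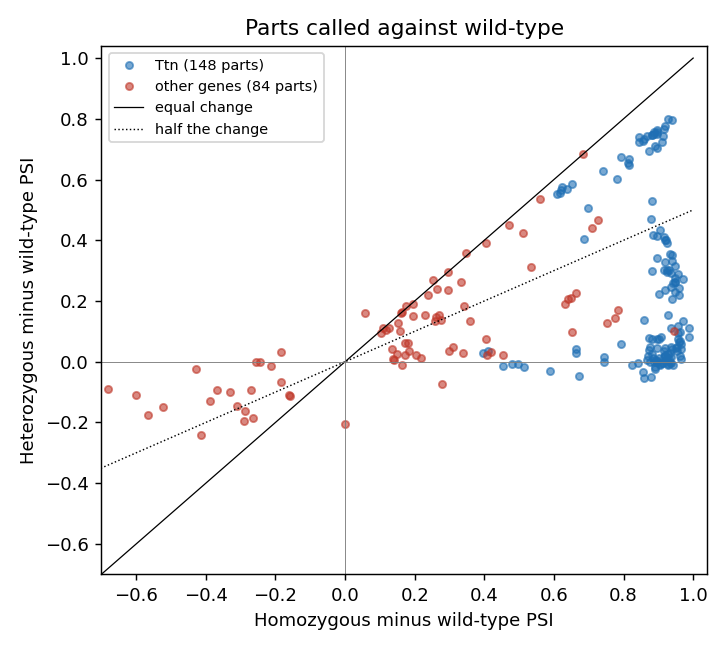
Difference in PSI between heterozygous and wild-type hearts (vertical axis) against that between homozygous and wild-type hearts (horizontal axis), each a fraction, with 1 point per part called against wild-type in either comparison. The 148 Ttn parts spread from no heterozygous change to nearly the full homozygous change, and part 250 has differences of 0.0814 and 0.987.

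The comparison of homozygous with heterozygous hearts asked where the second frameshift allele added to the first. Ttn again held most calls, with 110 of 147 parts, and parts of Ldb3, Ryr2 and Ank3 were also called. From heterozygous to homozygous hearts, Ttn part 250 rose by 0.905 (adjusted p = 1.25e-05), Ank3 part 117 by 0.631 (adjusted p = 5.41e-05), Ldb3 part 18 by 0.437 (adjusted p = 0.000358) and Ryr2 part 32 by 0.309 (adjusted p = 4.88e-05). Camk2d part 50 differed by 0.261 (adjusted p = 0.08) and Ttn part 293 by 0.129 (adjusted p = 0.717). Among the other named genes, 2310002L09Rik, Gm29015 and Ppp1r3b, a glycogen-targeting subunit of a phosphatase, rose by 0.842, 0.432 and 0.35, and Scube2 fell by 0.405. By limma, 134 parts were higher and 13 lower, in 23 gene identifiers, and 3858 parts had an unadjusted p under 0.05. The calls at Gm29015, Ppp1r3b and Scube2 were lost under 5, 10 and 13 of 20 alternatives.

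Gene expression, from summed inclusion reads, was compared between homozygous and wild-type hearts to follow Rbm20 itself and the state of the heart muscle. Rbm20 (ENSMUSG00000043639) fell from 113 ± 16 to 57.5 ± 7.49 CPM (n = 3 each, log2 fold change -0.98, SE 0.139, adjusted p = 0.00428). Genes of the cardiac stress response rose, led by Acta1, skeletal actin, from 204 ± 39.4 to 1440 ± 459 CPM (log2 fold change 2.82, SE 0.234, adjusted p = 0.000171). Nppb, which encodes the B-type natriuretic peptide, rose by 2.06 on the log2 scale (SE 0.35, adjusted p = 0.00987), and Ankrd1, a stretch-responsive nuclear and sarcomere protein, by 1.5 (SE 0.228, adjusted p = 0.00587). Xirp1 and Xirp2, actin-binding proteins of the intercalated disc, rose by 1.79 (adjusted p = 0.0163) and 1.24 (adjusted p = 0.00502).

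In all, edgeR called 969 of 22049 genes, 413 higher and 556 lower, of which 146 rose and 158 fell over 2-fold. At an unadjusted p under 0.05 there were 5001 genes. The number of calls was 2574 with DESeq2, 2384 with no low-count filter, 2207 with the replicate block and 297 with the library number covariate. It was 514, 307 and 295 without wild-type replicates 1, 2 and 3, and 309 and 380 without homozygous replicates 2 and 3.

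**Figure D3:**
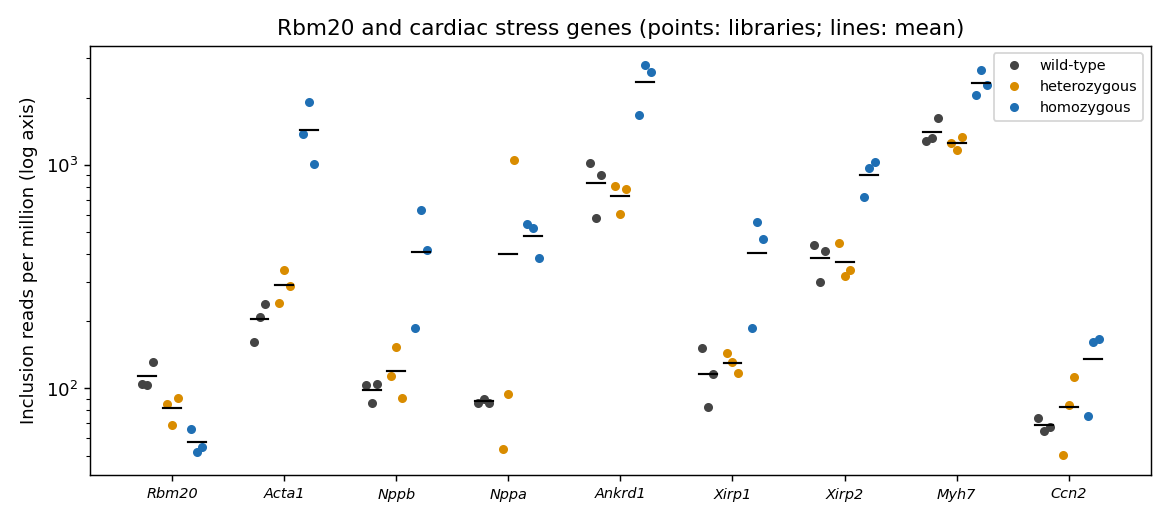
CPM (vertical axis, log scale) of Rbm20 and 8 cardiac stress genes (horizontal axis), with points for the libraries and lines for the mean of 3 libraries. Rbm20 was lowest in homozygous hearts, Acta1 was highest there, and 1 heterozygous library had 1050 CPM of Nppa.

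Of the 9 measured cardiac stress genes, 6 rose, and 8 when adjusted over the list alone, and fry found the list moving up (median log2 fold change 1.5, adjusted p = 0.0124). Nppa, the atrial natriuretic peptide, averaged 87.5 ± 1.91 in wild-type and 481 ± 86.4 CPM in homozygous hearts (log2 fold change 2.46, adjusted p = 0.12), Ccn2 had 0.97 (adjusted p = 0.0965) and Tnni1 1.25 (adjusted p = 0.342). Nppa passed without heterozygous replicate 3, which held 1050 CPM (adjusted p = 0.00018, range over the alternatives 1.57e-07 to 0.301). The call of Nppb was lost without wild-type replicate 2 and with the library number covariate, and that of Xirp1 without wild-type replicates 2 or 3 or homozygous replicates 2 or 3 and with the covariate. Myh7 had a log2 fold change of 0.73 (adjusted p = 0.00897), which turned to -0.10 (adjusted p = 0.795) with parts of a mean PSI of at least 0.95 only, and its adjusted p was 0.051 without wild-type replicate 2.

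Sarcomere and Z-disc genes rose in 16 of 37 cases with 0 falling, or 20 rising and 1 falling when adjusted over the list alone (median log2 fold change 0.34, fry adjusted p = 0.0124). The 16 include Myh7, whose rise was not kept with parts of a mean PSI of at least 0.95 only. They also include Fhl1 and Ldb3, which held parts with higher inclusion, and higher inclusion raises a sum of inclusion reads. Examples were Csrp3, a muscle LIM protein (1.05, adjusted p = 0.0141), Flnc, filamin C (1.38, adjusted p = 0.0217), Fhl1 (1.43, adjusted p = 0.00275) and Tcap, telethonin (0.73, adjusted p = 0.00302). Calcium handling and ion channel genes fell in 6 of 35 cases with 0 rising, or 10 falling and 1 rising when adjusted over the list alone (median -0.33, fry adjusted p = 0.0722). Among them were the pacemaker channel Hcn2 (-1.70, adjusted p = 0.000204), the potassium channel genes Kcnd2 (-1.23), Kcnj11 (-0.61) and Abcc9 (-0.74), and the calcium pump Atp2a2 (-0.58, adjusted p = 0.0499).

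Of 33 measured splicing regulators, 6 rose (Srsf2, Srsf6, Srsf7, Tra2a, Clk1 and Clk4) and 2 fell (Rbm20 and Rbfox1), or 12 and 5 when adjusted over the list alone (fry adjusted p = 0.588). The entry given as Clk4 is an identifier joined with an overlapping gene. Of the 28 RBM20 targets, 6 rose in expression, Ldb3, Enah, Lrrfip1, Pdlim5, Pdlim3 and Myh7, and 0 fell, or 7 and 1 when adjusted over the list alone (fry adjusted p = 0.965). A sum of inclusion reads also rises where parts are included more often. Myh7 turned to a log2 fold change of -0.10 with parts of a mean PSI of at least 0.95 only. Of 18 cell junction and nuclear envelope genes, Dsg2, a desmosomal cadherin, fell and 0 rose, or 1 each way when adjusted over the list alone (fry adjusted p = 0.494). Markers of fibroblasts, endothelium, smooth muscle, macrophages and leukocytes, erythroid cells and atria had 0 calls by edgeR, also when adjusted over the list alone, with fry adjusted p values of 0.965, 0.849, 0.9, 0.494, 0.965 and 0.965. Median, mean and fry direction differed in sign for the fibroblast, endothelial and smooth muscle markers, with medians of 0.04, -0.03 and 0.02 and a fry direction of down. Macrophage and leukocyte, erythroid and atrial markers had medians of -0.31, 0.24 and -2.28, the last over 5 measured genes. By its mixed test, fry gave adjusted p values of 6.6e-05 for RBM20 targets, 0.000894 for splicing regulators and 0.00437 for calcium handling and ion channels. They were 0.00033 for sarcomere and Z-disc and 0.000332 for cardiac stress genes. Cell junction and nuclear envelope genes had 0.174, and the marker lists 0.174 to 0.769.

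The largest named rises with at least 7 reads in each wild-type library were Lncbate10, a long noncoding RNA (log2 fold change 5.18, SE 0.564, adjusted p = 0.000939), Edn3, endothelin 3 (3.99, SE 0.305, adjusted p = 0.000136), St8sia1, a sialyltransferase of gangliosides (3.91, SE 0.27, adjusted p = 6.46e-05) and Syndig1 (3.85, SE 0.361, adjusted p = 0.000391). Gm49301, Gm20125, Gm36495, Gm34474, Odf3l1 and Fam229a rose from few reads, and Fam229a had 0 reads in each wild-type library and 11, 12 and 4 in the homozygous libraries. The 10 largest falls included 4 predicted genes that lie together on chromosome 4, Gm11757 (-7.26, SE 0.443, adjusted p = 5.28e-05), Gm13871, Gm11758 and Gm11756. Gm13871 and Gm11758 had equal or nearly equal counts in every library, so the 4 may not be separate falls. Pacsin1, a membrane-shaping adaptor, fell by 4.93 on the log2 scale (SE 0.524, adjusted p = 0.00078). Gprin2, Cyp1a1 and 2310016D03Rik also fell. Gm40658 (-7.28) had 6, 37 and 16 reads in the wild-type libraries and Nags (-6.73) 12, 10 and 18, and both had 0 in each homozygous library. Calls were lost under 2 to 9 alternatives at Gm20125, Gm36495, Gm34474, Odf3l1, Fam229a, Gprin2, Cyp1a1, 2310016D03Rik, Gm40658 and Nags.

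In heterozygous against wild-type hearts, edgeR called 0 genes, with 712 at an unadjusted p under 0.05, while DESeq2 called 22 genes, 15 higher and 7 lower, and edgeR with no low-count filter called 54. Rbm20 averaged 81.3 ± 11.5 CPM in heterozygous hearts (log2 fold change -0.48, SE 0.138, adjusted p = 1), which lay between the other genotypes. Acta1 had a log2 fold change of 0.51 and Nppb of 0.29, each with an adjusted p of 1, and all 9 measured stress genes had that adjusted p. None of the 12 lists had a called gene by edgeR, also when adjusted over the list alone. The lowest fry adjusted p for movement one way was 0.849, for smooth muscle markers, and the mixed test gave 0.769 for each list. Median and fry direction differed in sign for sarcomere and Z-disc genes, splicing regulators and atrial markers, with medians of 0.003, 0.02 and 3.03 and a fry direction of down. In heterozygous replicate 3 the atrial markers stood far above the other libraries, with Myl7 at 357 CPM against 28.1 in the next highest library, wild-type replicate 1, and Nppa had a log2 fold change of 2.20 with that library and -0.24 without it.

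The library names fall into 2 runs of numbers, and the later run held wild-type replicates 2 and 3 and heterozygous replicate 3 and no homozygous library, so homozygous and wild-type hearts could be compared within the earlier run against 1 wild-type library only. With the run as a covariate, limma called 180 parts for homozygous against wild-type, 37 for heterozygous against wild-type and 139 for homozygous against heterozygous, and edgeR called 297 and 0 genes. The fry tests of the lists were not rerun with this covariate.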

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

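Alternatives chosen after seeing the data were parts of a single gene only, removal of the Ttn junction reads of wild-type replicate 2, parts with a mean PSI of at least 0.95 only, and every alternative for the gene lists. The parts called in homozygous against wild-type hearts numbered between 173 and 292 under every alternative that counted parts, and those in homozygous against heterozygous between 115 and 208. The gene identifiers that held them were less steady. They numbered 56 and 23 in the main fit, and from 24 to 86 and from 10 to 51 under the alternatives. Ttn alone held 132 to 162 of the parts in homozygous against wild-type hearts. For heterozygous against wild-type the count of 42 parts became 12 gene identifiers, 15 parts on the logit scale, 22 with no filter on constant parts, 65 with the quasi-binomial test, 0 with only the 2 groups compared and 0 with the replicate block. In these last settings the RBM20 targets with a changed part were 0 in place of 2. Leaving out each library in turn gave 3 to 53 parts and 0 to 2 targets for heterozygous against wild-type, 1 to 52 parts in both comparisons, 1 to 3 lists, and 295 to 1319 genes in homozygous against wild-type expression. Lists past the threshold numbered 5 with no filter on constant parts and 5 with the quasi-binomial test, against 3. Expression calls in homozygous against wild-type numbered 2574 with DESeq2, 2384 with no low-count filter, 2207 with the replicate block and 297 with the library number covariate, against 969, and in heterozygous against wild-type 22 with DESeq2 and 54 with no low-count filter, against 0. Myh7 expression turned from 0.73 to -0.10 with parts of a mean PSI of at least 0.95 only. Apart from the unit counted and the fewer libraries, the cause was not tested.

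Of the values of named parts under all alternatives, 1447 stayed on the same side of the threshold, 210 lost a call and 10 gained one. Of those of named genes, 491 stayed on the same side, 74 lost a call, 8 gained one and 1 called value turned. Values that were not called and changed sign are counted among those that stayed. Those that stayed also include parts and genes with no call to lose in the main fit, so the losses fall on the called ones alone. Whether the replicate numbers pair the libraries was not settled. Residual PSI correlations between libraries of the same number ran from -0.0093 to 0.0365, and 5 of 9 libraries correlated best with their own number. With the numbers as a replicate block, 186, 0 and 126 parts were called in the 3 comparisons. In homozygous against wild-type expression the block raised the calls from 969 to 2207 genes. The pseudocount alternative was not run, since counts are given. In simulated data the tests found 8% of PSI changes of 0.2 and 35% of 1.5-fold changes, so smaller changes can be missed at this depth and group size. These shares hold for parts of intermediate inclusion and genes with many reads, the only ones changed in the simulations.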

Other observations

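A group of chromosome 4 genes among the largest falls in homozygous hearts lies beside the part that rose most outside Ttn. Gm11758, Gm11757, Gm13871 and Gm11756 span bases 73790456 to 73838997, and 2310002L09Rik begins at base 73857608. Gm11756 averaged 6.06 ± 0.0941 CPM in wild-type, 4.86 ± 0.605 in heterozygous and 0.0747 ± 0.0523 in homozygous hearts, while 2310002L09Rik rose in expression by 1.12 on the log2 scale in homozygous hearts (SE 0.134, edgeR adjusted p = 0.00161). Part 1 of 2310002L09Rik was included more often there, and higher inclusion also raises a sum of inclusion reads. Gm11758 and Gm13871 had equal or nearly equal counts in every library, 1312 and 1316 at the widest gap. The 4 falls may therefore not be separate measurements. Whether a sequence variant at this locus is their source was not tested. This locus was chosen after its values were seen.

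Homozygous and heterozygous hearts also differed in expression, with 112 genes higher and 97 lower in homozygous hearts by edgeR and 3104 genes at an unadjusted p under 0.05. Acta1 rose by 2.31 on the log2 scale (adjusted p = 0.00137), Ankrd1 by 1.69 (adjusted p = 0.00644), Xirp2 by 1.30 (adjusted p = 0.00865) and Nppb by 1.78 (adjusted p = 0.0418). Edn3 averaged 1.13 ± 0.558 CPM in wild-type, 3.29 ± 0.158 in heterozygous and 18 ± 2.57 in homozygous hearts. Along Rbm20, parts 2 to 10 held 0.341 to 0.428 of the wild-type CPM in homozygous hearts and parts 12, 13, 14, 16, 17, 18 and 19 held 0.484 to 0.592, while parts 1, 11 and 15 held 0.603, 1.25 and 1.01, without a test.

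All tests below were chosen after the result they address was seen, except the one on Nnt, and the rule for shared sequence variants was changed once after its first result. In its first form, with a single set of bounds, the result went with shared variants. The changed form asks for agreement over all bounds. In wild-type replicate 2, 339 exclusion reads spanned Ttn parts 3 to 386. A transcript made in all wild-type hearts is argued against by the highest number in the other wild-type libraries, 0. The Ttn calls did not rest on these reads, since 162 Ttn parts were called once they were removed, against 148. A rare transcript of this heart or an artefact of its library may be the source, and neither was tested.

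Heterozygous hearts followed homozygous hearts unevenly along Ttn. Of the 148 parts called in homozygous hearts, the heterozygous change was under 0.1 of the homozygous change in 72 and over 0.7 in 34. In every heterozygous library at least 27 parts were over 0.7 and at least 57 under 0.1. This argues against homozygous RNA mixed into the heterozygous libraries in a fixed proportion. Among the 41 parts of 270 to 300 bases, the shares at the 10th and 90th percentiles were 0.262 and 0.892. This gap of 0.629 argues against part length as the only source. Few of these 41 parts can lie under 0.1, so the test cannot tell whether the parts under 0.1 go with length. The junction reads of wild-type replicate 2 did not make the pattern, since 33 parts stayed over 0.7 and 73 under 0.1 without them. What sets the heterozygous share of each stretch stays open.

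In 11 parts of 8 genes outside Ttn, among them Pcnt, Ppa2, H2bc4 and Aox1, wild-type libraries stood apart and the heterozygous change was over 0.8 of the homozygous change. A difference between C57BL/6J and C57BL/6N mice, which differ by a deletion in Nnt, is argued against at that locus by a largest fold of 1.63 between wild-type and mutant means over 21 Nnt parts. Carry-over of chromosome 19 with the edited allele is argued against by 0 of the 8 genes lying there. Sequence variants shared by some mice whatever their genotype may be the source and cannot be told apart from an effect of the allele, since 4 of the 81 sets of 3 libraries that mix genotypes had as many genes with a PSI pattern of their own as the wild-type set (5 genes), and this number ran from 0 to 32 under other bounds on PSI and reads. The 3 homozygous libraries had 6 such genes and the highest mixed set 7. This count therefore cannot settle the question for homozygous changes outside Ttn either. An effect of the Rbm20 allele itself on the 8 genes stays open.

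With 3 libraries against 3, the 10 splits of the 6 libraries are too few to give a share under 0.05. The real split gave 230 parts in homozygous against wild-type hearts and the highest other split 2, with 42 and 5 in heterozygous against wild-type and 147 and 6 in homozygous against heterozygous. For expression the real and highest other numbers were 969 and 0 in homozygous against wild-type and 0 and 0 in heterozygous against wild-type.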
